A study of Mus musculus with 36 samples.

How the data were processed

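RNA of whole testis from juvenile mice was hybridised to Illumina mouse bead arrays of 45281 probes. The mice carried a knockout of Brdt or a deletion of its first bromodomain (BD1), and all carry the same strain label. Per the labels, RNA was extracted with Trizol. The 36 arrays came from 24 animals: arrays that share a mouse number, litter and testis weight were taken as 1 animal, although the series text speaks of 6 replicates per group. Groups, ages, litters and testis weights were taken from the labels. The labels do not say whether repeated arrays of an animal carry the same RNA.

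The authors deposited probe signals as intensity values on a linear scale, not normalized between arrays, which was exported with GenomeStudio 2011.1 per the submitters' processing notes. Whether background was subtracted is not given in the sources used here. The same deposited file holds a detection p-value for each probe and array. A matrix of the authors' processed values was also deposited, as intensity on a linear scale. In the values each of its columns has the probe order of its own array (lowest Spearman correlation 1) and nearly the same median (133.8 to 133.9), as quantile normalization without background correction would give, a step that no label states. The matrix was used as an alternative only. All 108 columns of both tables were used.

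Array medians lay between 118.3 and 152.9 and 75th percentiles between 222 and 346 before normalization, and 17379 to 20016 probes were detected per array at a detection p under 0.01. The number of arrays limits the precision of each value. Probes were named through the platform annotation, which gives 1 gene symbol for 34885 probes, several for 18 and none for 10378. Symbols of 34807 probes were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6, which was used only for names, chromosomes and gene order. Probes with several symbols or none were not named. The probes of multi-copy genes on chromosome Y and of the Speer, Magea, Klk1b and histone H4 families may bind several near-identical copies, so the gene is uncertain there.

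Signals were background-corrected by normexp, with negative control values inferred from the detection p-values, quantile-normalized and put on the log2 scale by neqc of limma 3.58.1 (offset 16) in R 4.3.3, with statmod 1.5.0 and version 1.17.8 of data.table. Arrays of an animal were averaged. Probes detected in at least 3 animals were kept (21190 probes), and each gene was represented by its probe with the highest mean, which gave 11529 genes. Of 4386 genes with several probes, the probes were called in opposite directions for 0 genes in the knockout at 17 dpp, 100 in the knockout at 20 dpp and 2 in the BD1 deletion. A linear model over all 6 groups was fitted with lmFit and eBayes with an intensity trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were the knockout against heterozygous animals at 17 dpp, the knockout against wild type at 20 dpp, the BD1 deletion against its controls at 20 dpp, both differences between these effects, controls at 20 against 17 dpp, and the control groups against each other. A gene detected on no array of its lower group has only a lower bound of its fold.

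The 21 gene lists were fixed before the data were examined. They hold spermatogonia, early meiotic prophase, pachytene and diplotene spermatocyte, meiotic G2/M and division, round spermatid, elongating spermatid, germ line chromatin, BET family, piRNA pathway, flagellum and cilia, spermiogenic transcription regulators, energy metabolism isozymes, retrogenes of X-linked parents, X-linked housekeeping, sex chromosome escape, apoptosis and checkpoint, Sertoli cell, Leydig cell, peritubular, vascular and blood cell, epididymis, and immediate early genes. Lists of at least 5 measured genes and all genes of chromosome X were tested with camera of limma (preset correlation 0.01), adjusted over 63 tests. Camera with an estimated correlation ended every call, with a lowest adjusted p of 0.175. Of 466 listed genes 346 were measured. Some genes stand in several lists, and the testis markers were not chosen on these samples. The list of retrogenes of X-linked parents also holds Y-linked genes such as Eif2s3y and Uba1y. The origin of its members, such as Hspb9 and Usp12, was not checked.

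Named genes followed a rule set before the data were examined. For each genotype comparison these are Brdt, the 10 called genes with the largest change each way that were detected in every animal of the higher group with no overlap between the animals of both groups, and up to 4 called members of each list with the smallest adjusted p. For the other comparisons they are the 5 called genes with the largest change each way. Other genes named were chosen after their values were seen. Testis weights were compared by exact two-sided permutation tests over animals, with the smaller tail doubled. Correlations of fold changes are across genes.

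The fit was tested on simulated data with 200 genes changed among 11529. Of genes changed by a log2 fold change of 0.5, 1 and 2, it recovered 31.5%, 87.5% and 99.5% in the knockout at 17 dpp, 21%, 89% and 96.5% in the knockout at 20 dpp, and 22%, 87.5% and 99.5% in the BD1 deletion. Up to 6.67% of the genes it called were unchanged. The simulated noise was independent between genes and animals, without litter or brightness, so recovery in the real data may differ. Alternatives were the authors' matrix, no background correction, median scaling, no detection filter, a stricter detection filter, repeated arrays kept separate with and without a block, 1 array per animal, litter as a block, fits of the compared groups alone, no intensity trend, array quality weights, every probe, a 2-fold minimum, subsets of controls and litters, testis weight as a covariate, and each animal left out. Scan brightness, doubtful animals, multi-copy genes and the centre of the fold changes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genome coordinates are not printed, since the build of the probe design is not given in the sources used here.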

Results

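Gene expression in mouse testis was measured on single-colour bead arrays in juvenile males that carried 1 of 2 altered alleles of Brdt, the testis-specific gene of the BET family of double bromodomain proteins. The knockout line was sampled at 17 and 20 days post partum (dpp), and a line that lacks the sequence of the first bromodomain (the BD1 deletion) was sampled at 20 dpp. At 17 dpp most germ cells are spermatocytes in meiotic prophase, and by 20 dpp round spermatids appear. The 36 arrays came from 24 animals. At 17 dpp there were 4 knockout and 6 heterozygous animals, and at 20 dpp 4 knockout and 3 wild-type animals of the same line. The BD1 line gave 3 homozygous and 4 control animals at 20 dpp, and this control group held heterozygous animals 219 and 191 and wild-type animals 195 and 196. Arrays of 1 animal were averaged, so that n counts animals. The 3 wild-type animals of the knockout line and knockout animals 148 and 152 at 20 dpp came from litter 1. Knockout animals 139 and 140 came from litter 2, without a wild-type littermate on the arrays. In the other genotype comparisons each litter held mutant and control animals, and the main fit had no litter term. The controls at 17 dpp were heterozygous, while those of this line at 20 dpp were wild type.

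Between 17379 and 20016 probes were detected per array, and the median signal lay between 118.3 and 152.9 intensity units. The number of arrays limits the precision of every value. Across probes, the median Pearson correlation was 0.990 between arrays of 1 animal and 0.983 between arrays of different animals of a group. Of the 24 arrays from animals with 2 arrays, 16 correlated best with the other array of the same animal within their group. Principal component 1 held 73.4% of the variance and separated the control animals at 20 dpp, with scores of 32.4 to 92.2, from the animals at 17 dpp, with scores of -81.4 to -21.7. The 4 knockout animals at 20 dpp lay at -38.4 to -3.50. Animals 139 and 140 of litter 2 lay within the range at 17 dpp, and animals 148 and 152 of litter 1, the litter of the wild types, lay above it. The BD1 deletion animals lay at 7.93 to 34.1.

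**Figure D1:**
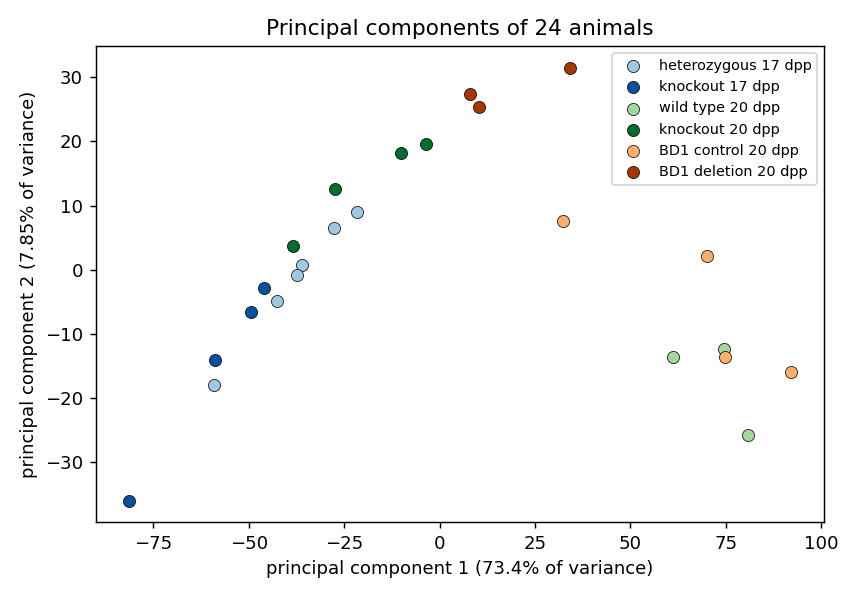
Scores of the 24 animals on principal components 1 and 2 of the normalized log2 signals, with 1 point per animal coloured by group. The knockout animals at 20 dpp (-38.4 to -3.50 on component 1) lie apart from the wild-type animals of the same age, and 1 BD1 control animal (32.4) lies among the BD1 deletion animals on component 1.

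Brdt transcript was lower in each mutant group than in its controls, with the least difference in the BD1 deletion. At 17 dpp the normalized log2 signal of the Brdt probe with the highest mean was 6.10 ± 0.64 (SD, n = 4) in knockout and 9.00 ± 0.37 (n = 6) in heterozygous animals, a log2 fold change of -2.90 ± 0.25 (SE), or 7.47-fold (limma, adjusted p = 7.53e-07). At 20 dpp it was 7.82 ± 0.52 (n = 4) in knockout and 11.5 ± 0.0894 (n = 3) in wild-type animals, a log2 fold change of -3.70 ± 0.30, or 13.0-fold (limma, adjusted p = 1.9e-09). In the BD1 line it was 10.3 ± 0.156 (n = 3) in homozygous and 11.4 ± 0.431 (n = 4) in control animals, a log2 fold change of -1.03 ± 0.30, or 2.04-fold (limma, adjusted p = 0.0323). In each of the 3 comparisons no mutant animal overlapped a control animal. Brdt was itself higher in controls at 20 dpp (11.5 and 11.4) than in heterozygous animals at 17 dpp (9.00), which also differed in genotype. A part of its fall that goes with maturation was therefore not separated from loss of the targeted transcript. In the knockout at 20 dpp Brdt also lay below heterozygous animals at 17 dpp (-1.19, limma, adjusted p = 0.00665). At 17 dpp the probe was detected on 4 of 6 knockout arrays, and with animals under the lowest detected signal raised to it the change was -2.79. Without background correction the change at 17 dpp was -1.82. The Brdt effect of the BD1 deletion differed from that of the knockout at 20 dpp by 2.67 ± 0.43 (limma, adjusted p = 0.00206), and the knockout effects at both ages did not differ past the threshold (-0.80 ± 0.39, limma, adjusted p = 0.131).

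Another Brdt probe gave log2 fold changes of -1.65 at 17 dpp and -2.30 at 20 dpp in the knockout, and -0.46 in the BD1 deletion, where it did not pass the test (limma, adjusted p = 0.167). A probe for Brdt that was detected on 0 arrays was not used. Where these probes lie relative to the deleted parts is not known, so a probe outside the deleted part would not check the labels. The call of Brdt in the BD1 deletion was lost with heterozygous controls only (-0.72, limma, adjusted p = 0.501). It was also lost without homozygous animal 193 (limma, adjusted p = 0.136) or 197 (0.115), and without control animal 219 (0.062), 195 (0.088) or 196 (0.13).

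**Figure D2:**
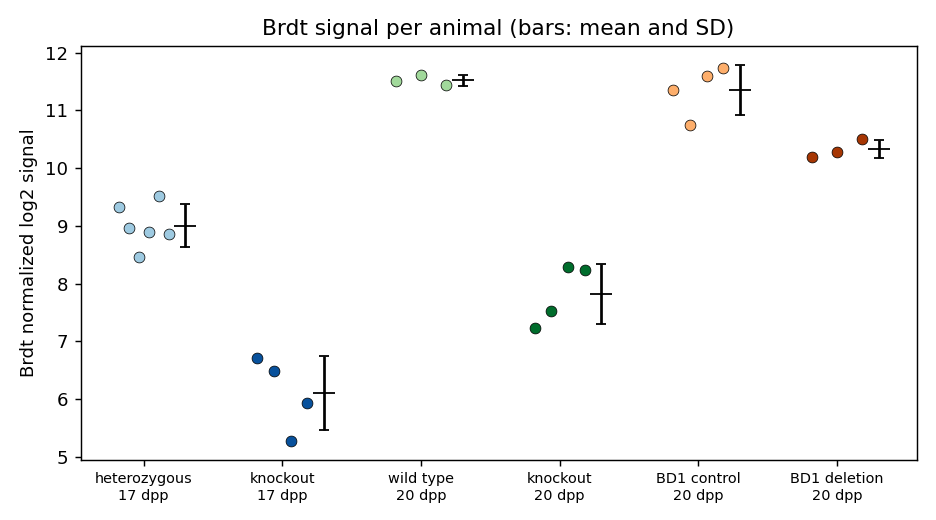
Normalized log2 signal of Brdt per animal, with 1 point per animal and bars for the group mean and SD. The knockout means are 6.10 at 17 dpp and 7.82 at 20 dpp against 9.00 and 11.5 in their controls, and the BD1 deletion mean is 10.3 against 11.4.

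Testis weight passed the permutation test in no comparison. At 20 dpp no difference could pass in either line, since the smaller tail was doubled and 35 splits then allow no exact p under 0.0571. Knockout testes weighed 0.667 mg more than heterozygous ones at 17 dpp (exact two-sided permutation test, p = 0.829, Benjamini-Hochberg adjusted 0.829 over 3 comparisons). At 20 dpp the difference was -2.3 mg in the knockout (exact p = 0.0571, adjusted 0.171), which is that smallest p. It was -2.39 mg in the BD1 deletion (exact p = 0.286, adjusted 0.429). Counting splits with as large an absolute difference, a form added after the data were seen that can reach 0.0286, gave exact p of 0.762, 0.0571 and 0.257 in the same order.

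At 17 dpp the knockout effect was read against heterozygous animals, and most changed transcripts were lower. The transcript of Adam3, which encodes a sperm surface protein, fell by 3.39 ± 0.57 on the log2 scale, and that of Hspb9, a small heat shock protein of the testis, had a log2 fold change of -3.13 ± 0.61. Zpbp2, a zona pellucida binding protein of the acrosome, fell by 2.06 ± 0.33, from 8.85 ± 0.706 (SD, n = 6) to 6.79 ± 0.735 (n = 4). Ccdc110 fell by 2.69, Mesp1, a transcription factor of early mesoderm, by 2.33, Ccdc192 by 1.96 and Rfx8 by 1.52. Adam3, Hspb9, Ccdc110 and Mesp1 were detected on 4, 4, 1 and 2 of 6 knockout arrays, and with animals under the lowest detected signal raised to it were at -3.07, -2.84, -2.06 and -2.08. Speer1 (-3.02) and Speer3 (-2.91) were also lower, but belong to a family of near-identical copies, which the probes do not clearly tell apart. Few transcripts were higher: Rdm1, a RAD52 motif protein, rose by 0.71 ± 0.11 and Ube2cbp by 0.68 ± 0.13, and the histone H4 gene H4c17 rose by 0.89, with the reserve that H4 genes are near-identical.

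Of 11529 genes tested with limma at an adjusted p under 0.05, 23 were higher and 131 lower in the knockout at 17 dpp, and 93 of the lower and 1 of the higher ones changed by at least 2-fold. The calls of Brdt, H4c17, Rdm1, Ube2cbp, Speer1, Speer3, Ccdc110, Mesp1, Zpbp2, Ccdc192, Rfx8 and Adam3 held with each animal left out. The other 17 of the 29 genes named by the rule lost their call without at least 1 animal. Among these, Hspb9 (limma, adjusted p = 0.067) and Catsperd, an auxiliary subunit of the CatSper channel (-1.70, adjusted p = 0.0108 with all animals, 0.057 without it), lost it without knockout animal 122 alone, and Piga, of GPI anchor synthesis (0.53), lost it without knockout animal 129 (0.056). Spag16, Dnali1, Tdrd6, Pgam2, Rfx4, Sycp2 and Pttg1, named with their lists, each lost it without knockout animal 122 (limma, adjusted p of 0.127, 0.241, 0.117, 0.158, 0.193, 0.161 and 0.16) or 129 (0.071, 0.096, 0.051, 0.075, 0.083, 0.074 and 0.117). The same 7 lost it without heterozygous animal 127 (0.072, 0.121, 0.083, 0.101, 0.107, 0.084 and 0.107) or 75 (0.059, 0.094, 0.067, 0.079, 0.088, 0.061 and 0.083). Without heterozygous animal 126 or 131 Dnali1 (0.101 and 0.096), Tdrd6 (0.069 and 0.067), Pgam2 (0.081 and 0.076), Rfx4 (0.081 and 0.082) and Sycp2 (0.061 and 0.059) were not called, nor was Pttg1 without 131 (0.082). Without background correction Dnali1, Pttg1 and Rfx4 were not called (limma, adjusted p of 0.0788, 0.128 and 0.0621). Without heterozygous animal 116 Dnali1 (0.058), Rfx4 (0.068), Sycp2 (0.058) and Pttg1 (0.058) were not called. Without animal 122, whose testis weighed 0.009 g, 50 genes were called, and without knockout animal 129 there were 52. Leaving out heterozygous animal 127, 131, 75 or 126 gave 50, 64, 67 or 68 genes, and leaving out heterozygous animal 121 gave 483. With litter as a block 1270 genes were called, and a fit of these 2 groups alone called 1 gene, Brdt (limma, adjusted p = 0.00162).

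Among the lists fixed before the data were examined, genes of flagellum and cilia were lower as a set at 17 dpp. Spag16, of the axonemal central apparatus, fell by 1.87 ± 0.41 and Dnali1, an axonemal dynein light chain, by 1.61 ± 0.41. In all, 2 of 26 measured members fell, and 21 when adjusted over the list alone (limma's camera, adjusted p = 2.05e-16; adjusted p = 0.23 with an estimated correlation). Of the pachytene and diplotene spermatocyte list, Adam3 and the chromatoid body gene Tdrd6 (-2.14 ± 0.49) fell, 2 of 22, or 12 adjusted over the list alone (camera adjusted p = 1.88e-13; adjusted p = 0.23 with an estimated correlation). Of the germ line energy metabolism isozymes, Pgam2, a phosphoglycerate mutase, fell by 2.48 ± 0.59, 1 of 16, or 10 adjusted over the list alone (camera adjusted p = 1.5e-08; adjusted p = 0.23 with an estimated correlation). The piRNA pathway list had 1 lower gene of 18, Tdrd6, or 4 adjusted over the list alone (camera adjusted p = 2.07e-06; adjusted p = 0.23 with an estimated correlation). Of the list named retrogenes of X-linked parents Hspb9 fell, 1 of 12, or 5 adjusted over the list alone (camera adjusted p = 0.000215, and 0.23 with an estimated correlation). Brdt itself and Rfx4 (-1.19 ± 0.29) were the 2 lower genes among 18 spermiogenic transcription regulators, 7 adjusted over the list alone (camera adjusted p = 0.000134; adjusted p = 0.242 with an estimated correlation).

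The remaining lists at 17 dpp held few calls. Sycp2, a synaptonemal complex protein, fell by 0.72 ± 0.16, 1 of 19 early meiotic prophase genes, or 5 adjusted over the list alone (limma's camera, adjusted p = 0.00727; adjusted p = 0.449 with an estimated correlation). Pttg1, which encodes securin, fell by 1.10 ± 0.27, 1 of 22 genes of meiotic G2/M and division both over all genes and adjusted over the list alone (camera adjusted p = 0.0291; adjusted p = 0.449 with an estimated correlation). Zpbp2 was the 1 lower gene of 31 in the round spermatid list, also adjusted over the list alone (camera adjusted p = 0.0284; adjusted p = 0.705 with an estimated correlation). No gene passed the test over all genes in the Sertoli cell list of 24, where 1 was higher adjusted over the list alone (median 0.22, camera adjusted p = 0.00158; adjusted p = 0.481 with an estimated correlation). X-linked housekeeping genes had a median of 0.15 with 0 of 28 called, also adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.623 with an estimated correlation). All 416 genes of chromosome X had a median of 0.15 with 4 higher, 2 adjusted over the list alone (camera adjusted p = 5.78e-07; adjusted p = 0.465 with an estimated correlation). The early meiotic prophase, meiotic G2/M, round spermatid and X-linked housekeeping calls were lost without knockout animal 122 (camera adjusted p of 0.302, 0.174, 0.18 and 0.173). The meiotic G2/M call was also lost without knockout animal 129 (0.0553) or heterozygous animal 127 (0.0779). Without both animals of the lowest testis weight the same 4 calls were lost (0.136, 0.117, 0.0731 and 0.0843), and the round spermatid call also with median scaling (0.107) and in a fit of these 2 groups alone (0.102). With fry of limma in place of camera these 4 and the Sertoli cell and chromosome X lists were not called (adjusted p of 0.164, 0.22, 0.61, 0.249, 0.114 and 0.0908). Camera called none of the spermatogonia, elongating spermatid, germ line chromatin, sex chromosome escape, apoptosis and checkpoint, Leydig cell, peritubular and blood cell, epididymis, and immediate early lists at 17 dpp.

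At 20 dpp the knockout lost most transcripts that mark spermatids. Prss21, a membrane-anchored serine protease of late germ cells, had a log2 signal of 5.30 ± 0.85 (SD, n = 4) in knockout and 11.7 ± 0.159 (n = 3) in wild-type animals and fell by 6.39 ± 0.54. Prss39, a serine protease of the acrosome, fell by 6.26 ± 0.44. Both were detected on only 3 of 6 knockout arrays, and with animals under the lowest detected signal raised to it their log2 fold changes were -5.99 and -6.00. Ankrd61 was at least 60.8-fold, Gtsf1l at least 42.3-fold, Znrf4, a ubiquitin ligase of spermatids, at least 36.1-fold and Spata45 at least 32.1-fold lower (limma, adjusted p of 2.84e-12, 2.42e-11, 1.39e-11 and 2.84e-12). These bounds hold for genes detected on no array of the lower group, and set the higher group's mean against the mean, over arrays, of the higher of the lowest detected signal and the probe's own signal. Ccna1, the cyclin required for the meiotic divisions in males, fell from 10.9 ± 0.425 (n = 3) to 5.88 ± 0.49 (n = 4), a log2 fold change of -5.03 ± 0.32 (limma, adjusted p = 6.09e-11).

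Transcripts of the multi-copy genes Gm20815, Gm20867, Ssty2 and Gm21943 on chromosome Y were among the largest falls in the knockout at 20 dpp, which is why the rule picked them. Gm20815 fell by 6.53 ± 0.69, Gm20867 by 6.09 ± 0.41, Ssty2, a spermatid-specific Y transcript, fell by 6.07 ± 0.43 and Gm21943 fell by 5.91 ± 0.37. The copies of these families are near-identical, so the gene named is uncertain. They were detected on 4, 3, 2 and 2 of 6 knockout arrays, and with the same floor were at -6.10, -5.63, -5.58 and -5.30. The largest increases were far smaller. Rdm1 rose by 1.74 ± 0.12, from 7.99 ± 0.0488 (n = 3) to 9.74 ± 0.0968 (n = 4), Kcnd2, a potassium channel, by 1.51 ± 0.33, Aqp2, a water channel, by 1.37 ± 0.39, Gal, which encodes galanin, by 1.36 ± 0.22 and Resf1 by 1.32 ± 0.28. Ptprn2, a phosphatase-like protein of secretory vesicles, was at least 1.87-fold higher (limma, adjusted p = 1.28e-06). Histone H4 genes H4c18, H4c17, H4c6 and H4c9 rose by 1.67, 1.57, 1.47 and 1.35, with the same doubt about near-identical copies.

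With limma, 6927 of 11529 genes were called in the knockout at 20 dpp, 4542 higher and 2385 lower, while 1255 were lower and 129 higher by at least 2-fold. The median log2 fold change of all genes was 0.24, against 0.14 without background correction and 0.28 with median scaling. Relative to the median of all genes, a setting added after the data were seen, 1715 genes were higher and 3304 lower (65.8% lower, against 34.4% around 0), so the larger number of higher genes depended on the centre. With litter as a block 5986 genes were called, and within litter 1 alone 4401. The 12 arrays of this comparison fell into 6 dimmer and 6 brighter ones. With brightness as a block 7053 genes were called, within the brighter arrays 6595, and within the dimmer arrays, which held knockout animals 148 and 152 of litter 1, 4357. Within the dimmer arrays Aqp2 (1.08, limma, adjusted p = 0.072) and Bcl2l11 (0.37, 0.0828) were not called, nor within the brighter ones Egr2 (0.44, 0.0659) and Klf4 (-0.65, 0.0511).

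The spermatid lists fell almost completely in the knockout at 20 dpp. With fry of limma in place of camera the round and elongating spermatid lists stayed called (adjusted p of 4.14e-07 and 4.17e-07). Of 31 round spermatid genes 28 were lower, also adjusted over the list alone, with a median of -2.82, or -2.77 with 15 undetected genes at their bound and -1.81 without background correction (limma's camera, adjusted p = 1.36e-19; adjusted p = 0.23 with an estimated correlation). Among them Acrv1 was at least 28.1-fold, Actl7a at least 27.6-fold, Spaca3 at least 26.9-fold and Spaca7 at least 18.4-fold lower (limma, adjusted p of 6.09e-11, 1.98e-10, 6.65e-12 and 4.43e-11). All 15 elongating spermatid genes measured were lower, also adjusted over the list alone, with a median of -3.32, or -2.7 with 7 at their bound and -1.74 without background correction (camera adjusted p = 3.36e-13; adjusted p = 0.23 with an estimated correlation). Odf1, of the outer dense fibres, fell by 5.6 ± 0.37 and Gsg1 fell by 5.87 ± 0.41 (-5.44 and -5.60 with the floor, each detected on 3 of 6 knockout arrays), and Hils1, a spermatid linker histone, and Smcp, of the mitochondrial capsule, were at least 24.3-fold and 19.6-fold lower (limma, adjusted p of 2.26e-10 and 2.71e-10). The median signal of the round spermatid list was 4.89 to 5.42 in the knockout animals, against 4.87 to 4.96 in heterozygous animals at 17 dpp and 8.91 to 10.1 in wild-type animals at 20 dpp.

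**Figure D3:**
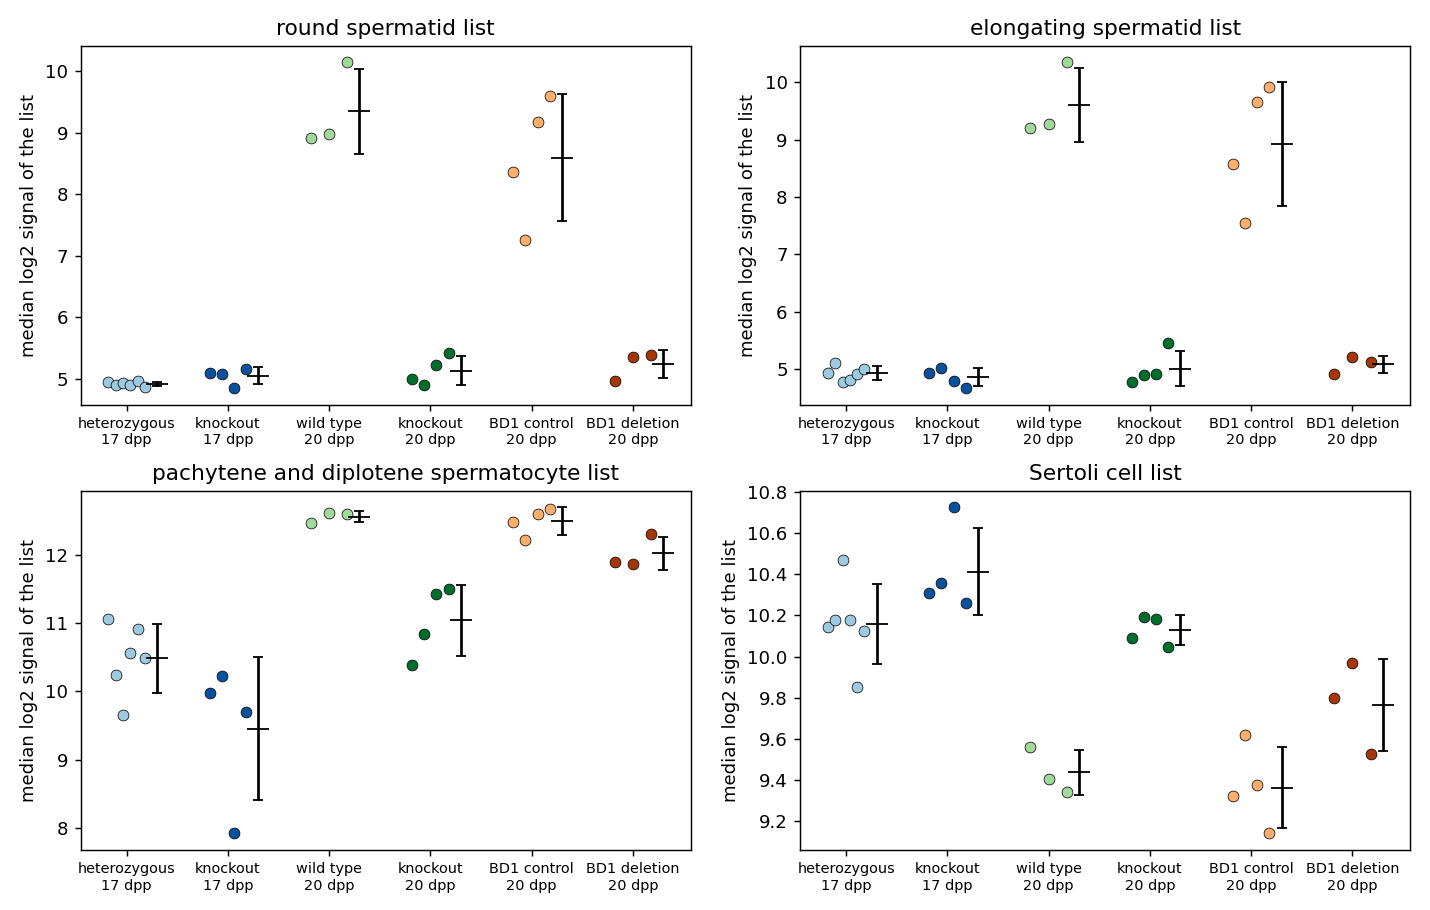
Median normalized log2 signal of 4 gene lists per animal, with 1 point per animal and bars for the group mean and SD. The round spermatid list lies at 4.89 to 5.42 in knockout animals at 20 dpp and at 8.91 to 10.1 in wild-type animals, and knockout animal 122 at 17 dpp has the lowest value of the pachytene and diplotene spermatocyte list (7.92).

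Spermatocyte, flagellar and metabolic lists were lower in part. Of 22 pachytene and diplotene spermatocyte genes 14 fell, 15 adjusted over the list alone (limma's camera, adjusted p = 6.42e-06; adjusted p = 0.449 with an estimated correlation), among them Ccna1, Acr, which encodes acrosin (-2.45 ± 0.46), Aurkc, a meiotic aurora kinase (-1.76 ± 0.28), and Cetn1, a centrin (-1.31 ± 0.25). Of 22 genes of meiotic G2/M and division 12 fell and 3 rose, 13 and 3 adjusted over the list alone (camera adjusted p = 0.00139; adjusted p = 0.266 with an estimated correlation). Aurka fell by 1.28 ± 0.20, and Ccnb3, a cyclin of early prophase, rose by 1.10 ± 0.19. Of 26 flagellum and cilia genes 23 fell, 24 adjusted over the list alone (camera adjusted p = 3.71e-09; adjusted p = 0.392 with an estimated correlation). Dnali1 fell by 2.90 ± 0.48 and Tekt5, a tektin, fell by 2.44 ± 0.30, and Dnaic2 was at least 2.71-fold and Ropn1 at least 1.54-fold lower (limma, adjusted p of 8.63e-08 and 0.000158). Of 16 energy metabolism isozymes 11 fell, also adjusted over the list alone (camera adjusted p = 1.2e-07; adjusted p = 0.23 with an estimated correlation). Gapdhs, the glycolytic dehydrogenase of sperm, was at least 8.78-fold and Acsbg2 at least 7.6-fold lower (limma, adjusted p of 2.06e-08 and 9.36e-09), and Hk1 fell by 1.72 ± 0.21. Of 18 spermiogenic transcription regulators 13 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.000428; adjusted p = 0.266 with an estimated correlation). Sox5 fell by 2.21 ± 0.29 and Creb3l4 by 1.88 ± 0.31, and Fhl5, a coactivator of CREM, was at least 6.65-fold lower (limma, adjusted p = 4.69e-06).

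Lists of chromatin genes, piRNA genes and retrogenes were mixed, and camera called none of them in the knockout at 20 dpp. Fry of limma called the chromatin and retrogene lists lower (adjusted p of 0.00532 and 0.0239) but did not call the piRNA list (0.505). Of 22 germ line chromatin genes 6 rose and 8 fell, also adjusted over the list alone, with a median of 0.01 and a mean of -0.74 (limma's camera, adjusted p = 0.0748). Dot1l, a histone H3 methyltransferase, fell by 1.06 ± 0.18 and Chd5, a chromatin remodeller, by 1.05 ± 0.18, and the H2B-like gene H2bl1 was at least 3.57-fold lower (limma, adjusted p = 4.02e-05). Of 18 piRNA pathway genes 4 rose and 5 fell, 4 and 4 adjusted over the list alone (camera adjusted p = 0.25). Henmt1, the piRNA methyltransferase, fell by 1.62 ± 0.25 and Tdrd7 by 0.99 ± 0.19. Of 12 genes of the retrogene list 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0561). Pgk2, the autosomal phosphoglycerate kinase of germ cells, fell by 3.06 ± 0.63 and Tktl2 fell by 2.20 ± 0.27, while Usp12 rose by 0.63 ± 0.15. In the BET family list of 3 measured genes, too few for a set test, Brdt and Brd2 (-0.36 ± 0.12) were lower and Brd3 (0.29 ± 0.11) was higher, also adjusted over the list alone. The call of Brd3 was lost relative to the median of all genes (0.05, limma, adjusted p = 0.741) and without knockout animal 139 (0.069) or 140 (0.062) or wild-type animal 149 (0.064) or 157 (0.104). With litter as a block it was also lost (0.19, limma, adjusted p = 0.196). Within litter 1 alone Brd2 (-0.30, limma, adjusted p = 0.0989) and Brd3 (0.19, 0.232) were not called, nor within the dimmer arrays (-0.35, 0.0612, and 0.21, 0.199).

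Lists of chromosome X, Sertoli cell and Leydig cell genes were higher in the knockout at 20 dpp. Of 28 X-linked housekeeping genes 25 rose, also adjusted over the list alone, with a median of 0.74 against 0.24 for all genes (limma's camera, adjusted p = 1.67e-05; adjusted p = 0.449 with an estimated correlation). Tktl1 rose by 1.02 ± 0.16, Cstf2 by 0.81 ± 0.15, Hprt, of purine salvage, by 0.77 ± 0.14 and Ndufa1, of respiratory complex I, by 0.76 ± 0.10. Of all 416 genes tested on chromosome X, 309 were higher and 43 lower, 314 and 43 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 2.84e-07; adjusted p = 0.455 with an estimated correlation). Of 24 Sertoli cell genes 20 rose, 21 adjusted over the list alone, with a median of 0.60 (camera adjusted p = 0.000308; adjusted p = 0.449 with an estimated correlation). Trf, which encodes transferrin, rose by 1.04 ± 0.21, Defb36 by 0.96 ± 0.19, the inhibin subunit gene Inha by 0.88 ± 0.15 and Dhh, which encodes desert hedgehog, by 0.78 ± 0.16. Of 14 Leydig cell genes 9 rose, also adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.0284; adjusted p = 0.449 with an estimated correlation). Akr1cl rose by 1.01 ± 0.15, the retinaldehyde dehydrogenase gene Aldh1a1 by 0.92 ± 0.19 and Cyb5a by 0.63 ± 0.12. With the authors' matrix, without background correction and with median scaling these 4 lists kept their direction and call, and the Leydig cell call was lost within litter 1 alone (camera adjusted p = 0.0567) and within the dimmer arrays (0.086).

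Camera did not call the remaining lists in the knockout at 20 dpp. Among 18 spermatogonia genes 11 rose, also adjusted over the list alone, with Sohlh1 at 0.79 ± 0.18 and the stem cell factor receptor gene Kit at 0.72 ± 0.15 (limma's camera, adjusted p = 0.0656). Among 19 early meiotic prophase genes 10 rose and 3 fell, 11 and 3 adjusted over the list alone (camera adjusted p = 0.41). Tex11 rose by 1.07 ± 0.20 and Meiob, of meiotic recombination, by 0.79 ± 0.14, while the cohesin gene Stag3 fell by 0.40 ± 0.08. Among 20 apoptosis and checkpoint genes 10 rose and 1 fell, 10 and 0 adjusted over the list alone (camera adjusted p = 0.126), with the damage kinase gene Atm at 0.94 ± 0.16, pro-apoptotic Bcl2l11 at 0.75 ± 0.14, and Gadd45g and Gadd45a both at 0.72. Among 7 sex chromosome genes of the escape list 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.404). Usp9y rose by 0.89 ± 0.18, Zfy1 by 0.88 ± 0.17 and Zfx by 0.74 ± 0.16, and multi-copy Sly fell by 3.57 ± 0.26. Among 24 genes of peritubular, vascular and blood cells 6 rose, also adjusted over the list alone (camera adjusted p = 0.321), with the macrophage genes Lyz2 at 1.06 ± 0.25 and Csf1r at 0.82 ± 0.19. Of 6 epididymis genes 2 rose, Wfdc10 (0.94 ± 0.19) and Eppin (0.69 ± 0.17), and 1 fell, Foxj1 (-0.50 ± 0.19), also adjusted over the list alone (camera adjusted p = 0.699). The call of Foxj1 was lost without knockout animal 139 (limma, adjusted p = 0.08), 140 (0.062) or 148 (0.066) or wild-type animal 149 (0.106) or 157 (0.072), and with litter as a block (-0.36, limma, adjusted p = 0.193), and it was detected on 1 of 6 knockout arrays (-0.23 with the floor). Of 15 immediate early and stress genes 4 rose and 3 fell, also adjusted over the list alone, among them Egr2 (0.66 ± 0.17), Klf4 (-0.92 ± 0.26) and the chaperone gene Dnajb1 (-0.60 ± 0.12). This list had a median of 0.27 while camera pointed lower (adjusted p = 0.879).

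The BD1 deletion lowered several genes named above for the knockout at 20 dpp. Spaca3 had a log2 signal of 4.65 ± 0.186 (SD, n = 3) in homozygous and 9.38 ± 0.945 (n = 4) in control animals and was at least 14.4-fold lower, and Acrv1 was at least 14.1-fold, Spata45 at least 19.4-fold and Tmem247 at least 16-fold lower (limma, adjusted p of 7.24e-10, 6.18e-09, 7.16e-10 and 1.62e-08). Ankrd61 fell by 4.99 ± 0.32 and Gtsf1l by 4.62 ± 0.37 (-4.92 and -4.35 with the floor, each detected on 4 of 6 arrays of homozygous animals). The Y-linked genes Gm20815, Ssty2, Gm21943 and Gm20867 had log2 fold changes of -5.42, -5.20, -5.16 and -4.64, again with uncertain identity among near-identical copies. They were detected on 5, 1, 2 and 4 of 6 arrays of homozygous animals, and with the floor were at -5.40, -4.82, -4.71 and -4.57. Ccna1 fell by 1.38 ± 0.32, from 11.2 ± 0.565 (n = 4) to 9.84 ± 0.494 (n = 3) (limma, adjusted p = 0.00705), a call that was lost without homozygous animal 193 (limma, adjusted p = 0.072). Higher transcripts included Pbld2 (1.18 ± 0.23), Rdm1 (1.01 ± 0.12), the integrin gene Itga11 (0.97 ± 0.17) and 2610524H06Rik (0.93 ± 0.15). The H4 genes H4c17, H4c18 and H4c6 rose by 1.21, 1.05 and 0.98.

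With limma, 1110 of 11529 genes were called in the BD1 deletion, 372 higher and 738 lower, and 471 were lower and 8 higher by at least 2-fold. Relative to the median of all genes (0.12), a setting added after the data were seen, 50 were higher and 1077 lower (95.6% lower, against 66.5% around 0). Control animal 191, heterozygous and of litter 4, had the lowest round spermatid list median of the controls, 7.26 against 8.35 to 9.59, and without it 3428 genes were called. Without homozygous animal 193 or 197 or control animal 196 or 195 the count was 515, 555, 545 or 706. It was 2972 against wild-type controls only, 326 against heterozygous controls only, 2502 with litter as a block and 331 in a fit of these 2 groups alone. Of the 48 genes named by the rule, 33 kept their call with each animal left out.

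Spermatid lists led the lower genes of the BD1 deletion. With fry of limma in place of camera the round and elongating spermatid lists stayed called (adjusted p of 6.39e-06 and 1.17e-05). Of 31 round spermatid genes 19 fell, 25 adjusted over the list alone, with a median of -2.36, or -1.89 with 12 at their bound and -1.19 without background correction or with the authors' matrix (limma's camera, adjusted p = 4.16e-30; adjusted p = 0.175 with an estimated correlation). Spaca7 fell by 4.45 ± 0.33, and Spam1, the sperm hyaluronidase, was at least 8.37-fold lower (limma, adjusted p = 9.28e-09). Of 15 elongating spermatid genes 10 fell, 14 adjusted over the list alone, with a median of -2.92, or -2.11 with 8 at their bound and -1.60 without background correction (camera adjusted p = 1.42e-19; adjusted p = 0.175 with an estimated correlation). Gsg1 fell by 4.37 ± 0.41 and Odf1 fell by 4.34 ± 0.37, and Hils1 and Smcp were at least 12.3-fold and 10.6-fold lower (limma, adjusted p of 1.63e-08 and 2.87e-08). Of 22 germ line chromatin genes 5 fell, with 1 higher and 8 lower adjusted over the list alone, a median of -0.05 and a mean of -0.67, so that a few members carried the call (camera adjusted p = 0.0124, and 0.0668 against heterozygous controls only; adjusted p = 0.23 with an estimated correlation), among them H2bl1, at least 3-fold lower (limma, adjusted p = 0.000334). Of 16 energy metabolism isozymes 5 fell, also adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.266 with an estimated correlation). Gapdhs was at least 5.14-fold lower (limma, adjusted p = 6.04e-07), Acsbg2 fell by 2.93 ± 0.34 and the alcohol dehydrogenase gene Adh4 by 1.25 ± 0.20. Spaca7 and Acsbg2 were each detected on 1 of 6 arrays of homozygous animals, and with the floor were at -3.76 and -2.24. Of 18 spermiogenic transcription regulators 5 fell, also adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.348 with an estimated correlation). Sox5 fell by 2.02 ± 0.29 and Fhl5 was at least 3.96-fold lower (limma, adjusted p = 0.0002).

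Fewer members of the other lists passed the test in the BD1 deletion. Of 26 flagellum and cilia genes 2 fell, also adjusted over the list alone (camera adjusted p = 3.6e-05, and 0.492 with an estimated correlation). Dnaic2 fell by 1.85 ± 0.25 and was detected on 1 of 6 arrays of homozygous animals (-1.32 with the floor). Ropn1 was at least 1.56-fold lower (limma, adjusted p = 0.000377). Of 22 pachytene and diplotene genes 3 fell, also adjusted over the list alone, Ccna1, Cetn1 (-0.84) and Aurkc (-0.87) (camera adjusted p = 0.00197; adjusted p = 0.576 with an estimated correlation). Of 22 meiotic G2/M genes 2 fell, Ccna1 and Aurkc, and 1 adjusted over the list alone (camera adjusted p = 0.00727; adjusted p = 0.392 with an estimated correlation). Of 12 genes of the retrogene list 2 fell, also adjusted over the list alone, Tktl2 (-1.38 ± 0.27) and Cetn1 (camera adjusted p = 0.0291, and 0.449 with an estimated correlation). X-linked housekeeping genes had a median of 0.26, with 0 of 28 called, also adjusted over the list alone (camera adjusted p = 0.0128; adjusted p = 0.623 with an estimated correlation). The retrogene and X-linked housekeeping calls were lost without homozygous animal 193 (camera adjusted p of 0.0604 and 0.0639) and without control animal 196 (0.0618 and 0.0529), and the latter also without homozygous animal 197 (0.0617). Against heterozygous controls only both were lost (0.163 and 0.201), and the retrogene call also without litter 4 (0.0547) and with genes detected on every array of a group (0.0517). With fry of limma in place of camera the retrogene, X-linked housekeeping, flagellum and cilia, meiotic G2/M, and pachytene and diplotene lists were not called (adjusted p of 0.0979, 0.0908, 0.141, 0.0655 and 0.251). Of 24 Sertoli cell genes 2 rose, Gdnf (0.54 ± 0.16) and Sox9 (0.42 ± 0.12), and 7 adjusted over the list alone (camera adjusted p = 0.00255; adjusted p = 0.492 with an estimated correlation).

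Several of these small changes rested on single animals or on the centre. The calls of Gdnf, Sox9, Cetn1 and Aurkc were each lost without homozygous animal 193 (limma, adjusted p of 0.105, 0.097, 0.214 and 0.223), 197 (0.236, 0.216, 0.129 and 0.205), control animal 219 (0.073, 0.071, 0.09 and 0.102) or 196 (0.123, 0.151, 0.134 and 0.189). Those of Gdnf and Aurkc were also lost without control animal 195 (0.112 and 0.1). Gdnf and Sox9 were not called relative to the median of all genes (0.42 and 0.30, limma, adjusted p of 0.124 and 0.141). Against heterozygous controls only Gdnf, Sox9, Cetn1, Aurkc, Ccna1, Tktl2, Pbld2, Klf4, Bcl2l11 and Sohlh1 were not called (limma, adjusted p of 0.479, 0.378, 0.288, 0.53, 0.258, 0.113, 0.0862, 0.38, 0.185 and 0.431), nor without background correction Gdnf and Sohlh1 (0.0634 and 0.0547). Of the lists that camera did not call, spermatogonia had 1 higher gene of 18, Sohlh1 (0.55 ± 0.18), and 0 adjusted over the list alone. Without homozygous animal 193 (limma, adjusted p = 0.233) or 197 (0.171) or control animal 219 (0.103), 195 (0.058) or 196 (0.212) Sohlh1 was not called. Apoptosis and checkpoint had 1 higher gene of 20, Bcl2l11 (0.61 ± 0.14, not called without homozygous animal 197, limma, adjusted p = 0.106), and immediate early and stress 1 lower gene of 15, Klf4 (-1.03 ± 0.26, not called without control animal 196, 0.059), both also adjusted over the list alone. The sex chromosome escape list had 1 lower gene of 7, Sly, at least 4.86-fold (limma, adjusted p = 3.67e-08), also adjusted over the list alone, with a median of 0.26 and a mean of -0.20. The early meiotic prophase, piRNA pathway, Leydig cell, peritubular and blood cell, and epididymis lists held 0 calls over all genes. Of the lists that camera did not call in the BD1 deletion, fry of limma called only apoptosis and checkpoint (higher, adjusted p = 0.0219). Of the 416 genes of chromosome X 11 were higher and 41 lower, 16 and 42 adjusted over the list alone (median 0.26, camera adjusted p = 0.0824).

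The effects of both alleles at 20 dpp were compared with each other in the same fit. Prss39, Prss21 and Ccna1 were lower in the knockout by far more than in the BD1 deletion, with differences of the log2 fold changes of 4.81 ± 0.62, 4.67 ± 0.77 and 3.65 ± 0.46 (limma, adjusted p of 0.000166, 0.00261 and 0.000133). Prss39 fell by 6.26 in the knockout and by 1.45 in the BD1 deletion, and Prss21 fell by 6.39 and 1.71. Ccdc178 and Gm9748 differed by 4.13 ± 0.78 and 3.41 ± 0.52. In the opposite direction Vsig10 differed by -1.28 ± 0.17 and H2bfm by -1.06 ± 0.18, and Vsig10 was higher in the knockout (0.68) and lower in the BD1 deletion (-0.59). Oasl2 (-1.36), Magea6 (-1.06, of a family of near-identical copies) and Ccng2 (-0.98) also differed, but these 3 calls were lost without at least 1 animal. Each was lost without homozygous animal 222 (limma, adjusted p of 0.091, 0.196 and 0.169) and without wild-type animal 149 (0.064, 0.16 and 0.085) or 157 (0.061, 0.159 and 0.153). Magea6 was also not called without animal 139 (0.093), 140 (0.114), 148 (0.053), 191 (0.095), 193 (0.07), 197 (0.063) or 219 (0.091), and Ccng2 without 139 (0.091), 140 (0.085), 146 (0.051), 195 (0.076), 197 (0.065) or 219 (0.073). With litter as a block Magea6 (-0.91, limma, adjusted p = 0.121) and Ccng2 (-0.76, 0.145) were not called, nor without background correction (0.0845 and 0.0611).

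In all, 144 genes differed between the alleles (limma), 126 with a higher and 18 with a lower value in the BD1 deletion. The count was 31 without homozygous animal 222, 35 and 40 without wild-type animals 149 and 157, 63 and 65 without knockout animals 140 and 139, 83 without control animal 191 and 303 without control animal 196. A fit of the groups compared alone gave 52. Both alleles lowered 721 genes, of the 2385 and 738 lower in each, against 152.67 for independent lists, and raised 338, of 4542 and 372, against 146.55. In each direction 1 gene was called the opposite way. The log2 fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.89 and a Spearman rho of 0.81, and the slope of the BD1 deletion on the knockout was 0.56. These 2 comparisons shared no animals. The shared count of 1059 genes was 498, 533, 531 or 678 without homozygous animal 193 or 197 or control animal 196 or 195, and 3174 without control animal 191.

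**Figure D4:**
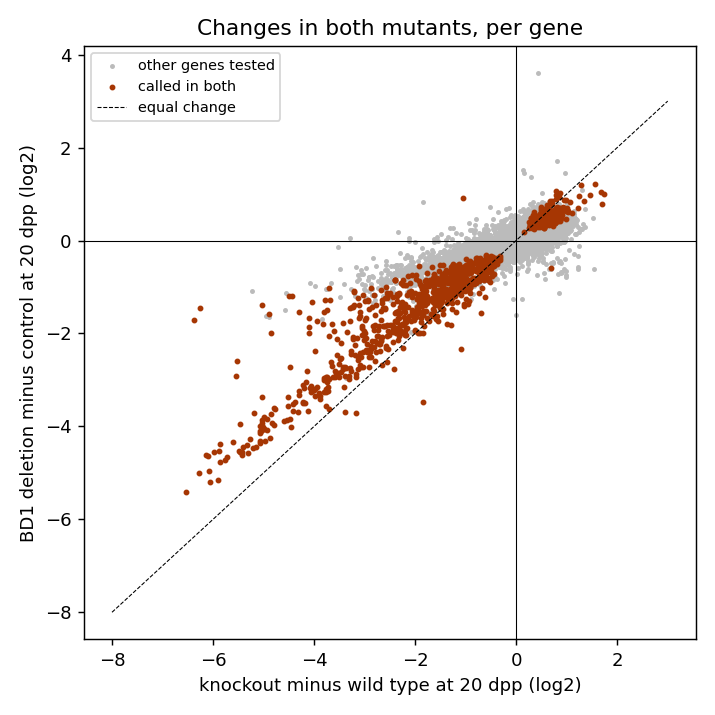
Log2 fold change of each gene tested in the knockout (x axis) and in the BD1 deletion (y axis) at 20 dpp, with genes called in both comparisons in red and a dashed line of equal change. Most red genes lie below 0 on both axes and above the dashed line, and the slope over all genes is 0.56.

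Between 17 and 20 dpp the knockout effects were compared with each other in the same fit. Ankrd61, Znrf4 and Spata45 differed between the ages by -6.30 ± 0.42, -6.11 ± 0.45 and -6.07 ± 0.41 (limma, adjusted p of 8.2e-10, 3.62e-09 and 8.2e-10), and the multi-copy genes Gm20815 and Gm20867 by -6.59 and -6.16. Ankrd61, Znrf4 and Spata45 were detected on no knockout array at 20 dpp, so their differences rest on signals below detection and are not exact. Gm20815 and Gm20867 were detected there on 4 and 3 of 6 knockout arrays. Gal, Kcnd2, Chp2, Resf1 and Nr1d2, a nuclear receptor of the circadian clock, had effects that were higher at 20 dpp by 1.27, 1.59, 1.27, 1.27 and 1.25. In all 2687 genes differed, 1424 with a higher and 1263 with a lower effect at 20 dpp (limma), and the control genotype differed between the ages. The count was 1305 and 1466 without wild-type animals 157 and 149 and 1755 without knockout animal 139. The calls of Kcnd2 (limma, adjusted p = 0.055), Chp2 (0.06) and Resf1 (0.053) were lost without wild-type animal 149, and those of Chp2 (0.054), Resf1 (0.056) and Nr1d2 (0.078) without wild-type animal 157. With litter as a block Chp2 (0.72, limma, adjusted p = 0.0866), Resf1 (0.77, 0.123) and Nr1d2 (0.72, 0.142) were not called. Both ages shared 116 lower genes, of 131 and 2385, against 27.1 for independent lists, and 16 higher genes, of 23 and 4542, against 9.06. These shared calls numbered 45 without knockout animal 122 (28 lower and 17 higher) or 129 (40 and 5), and 47, 51, 59 and 60 without heterozygous animals 127, 75, 131 and 126. They numbered 86, 81 and 80 without wild-type animals 146, 149 and 157, and 404 without heterozygous animal 121.

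In controls, animals of both ages differed in genotype, line and litter as well as in age. From heterozygous animals at 17 dpp to the controls at 20 dpp Gtsf1l rose by 6.05 ± 0.27 and the multi-copy Y genes Gm20815, Gm20867, Ssty2 and Gm21943 by 7.95, 6.37, 6.16 and 6.15. BC034090 fell by 2.07 ± 0.22, and Gm15107 (-1.88), the thioesterase gene Acot1 (-1.82), Arhgap22 (-1.80) and the semaphorin gene Sema5a (-1.76) were also lower. With limma 3203 genes were higher and 5724 lower at 20 dpp (median of all genes -0.25). For the knockout, age genes were taken from the BD1 line's controls, so that no 20 dpp animal stood on both sides. Of 3088 genes that rose with age 2204 were lower in the knockout and 33 higher, and of 5322 that fell with age 3840 were higher and 11 lower. Across genes the knockout effect and the age effect had a Pearson r of -0.91, a Spearman rho of -0.83 and a slope of -0.84. With an estimated correlation camera gave unadjusted p of 0.000113 for the rising and 0.00217 for the falling genes. For the BD1 deletion, with age genes from the wild-type animals of the knockout line, 715 of 2986 rising genes were lower and 318 of 5242 falling genes higher, with a Pearson r of -0.84, a Spearman rho of -0.77 and a slope of -0.47 (camera with an estimated correlation, unadjusted p = 0.00229 and 0.0132).

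The control groups of both lines at 20 dpp also differed in some genes. Lrrc18 was at least 4.73-fold and Oit1 at least 6.2-fold higher, and Cmya5 at least 5.38-fold and Ttc22 at least 1.79-fold lower, in the wild-type animals of the knockout line than in the controls of the BD1 line (limma, adjusted p of 2.01e-13, 2.86e-07, 2.71e-08 and 0.00368). Cdh24, a cadherin, was higher by 3.15 ± 0.38 and Wdfy1 by 2.28 ± 0.18, while Gm2897, Gm3696 and Gm5796 were at -2.08, -1.80 and -1.78. Ndufb10, of respiratory complex I, was higher by 3.31 ± 0.67, a call lost without wild-type animal 157 (limma, adjusted p = 0.059). In all 197 genes differed, 76 higher and 121 lower. The count was 64, 75 and 85 without wild-type animals 157, 146 and 149, 115 without control animal 219, and 58 in a fit of these 2 groups alone.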

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

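The tests of normalization, of a delay at 20 dpp, of the share of spermatids and of litter were chosen only after the result was seen, as were the jackknife, the matched genes, the single autosomes and the straight lines for chromosome X. Those of animal 122, of a delay at 17 dpp, of chromosome X by a smooth curve and of other splits of the animals were set before.

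An animal apart from the rest of its group was sought by the gap to its nearest neighbour over the group's range, which chance exceeds in about 1 in 20 groups. Knockout animal 139 at 20 dpp had a testis weight of 0.018 g, against 0.0212 to 0.0215 g in the others. Heterozygous animal 121 at 17 dpp had a median log2 signal of 8.49 in the list of spermiogenic transcription regulators, against 8.85 to 9.01 in the others. These were 2 of 104 summary values. Among named genes 33 of 624 pairs of gene and group had an animal apart, 10 of them knockout animal 122.

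The knockout effect differed between 17 and 20 dpp in 2687 genes by a test of the difference itself (limma). The 10 genes named by the rule were Kcnd2 (1.59), Chp2 (1.27), Resf1 (1.27), Gal (1.27), Nr1d2 (1.25), Gm20815 (-6.59), Ankrd61 (-6.30), Gm20867 (-6.16), Znrf4 (-6.11) and Spata45 (-6.07). The values of Ankrd61, Znrf4 and Spata45 are not exact, since no knockout array at 20 dpp detected them. Other splits of the animals gave up to 5617 genes, 6 of 100 gave as many as the real 2687, and chance could not be excluded. The effects of both alleles at 20 dpp differed in 144 genes, by the same kind of test, among them Prss39 (4.81), Prss21 (4.67), Ccdc178 (4.13), Ccna1 (3.65), Gm9748 (3.41), Oasl2 (-1.36), Vsig10 (-1.28), Magea6 (-1.06), H2bfm (-1.06) and Ccng2 (-0.98). Here 9 of 100 splits gave as many, up to 5672 genes, so chance could not be excluded, and a split with several times the real count points to a structure of the samples. Without knockout animal 139 the counts were 1755 and 65. Without wild-type animals 149 and 157 they were 1466 and 1305 genes between the ages, and 35 and 40 between the alleles. The count between the alleles was also 31 without homozygous animal 222, 63 without knockout animal 140, 83 without control animal 191 and 303 without control animal 196.

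The first pattern weighed is the loss of spermatid transcripts at 20 dpp. Normalization was excluded as its cause, since over 4 scalings the highest median of the round spermatid list relative to all genes was -1.94 in the knockout and -1.26 in the BD1 deletion. A smaller share of spermatids alone would raise all other cell types alike. In the knockout the values argued against it without excluding it. Sertoli cell genes rose (0.60) and pachytene and diplotene genes fell (-1.14, with 14 of 22 lower and 0 higher). Some of the latter are also spermatid transcripts. Of the 6 not called as rising with age 0 were called lower (median -0.37), and spermatids may express these as well. Sertoli cell genes still exceeded them by 0.966 (0.611 to 1.23 by a bootstrap that takes genes as independent). Per animal no knockout overlapped a wild type in this difference (exact permutation of the absolute difference, p = 0.0286, the smallest that 35 splits allow). For the BD1 deletion the value was 0.376 (0.119 to 0.669 over genes, exact permutation p = 0.229 over animals), so there it was left open by the spread over animals. A delay in maturation alone may account for the lower spermatid transcripts of the knockout. Of 1324 genes that rise with age and had room to fall, 0.755% lay below heterozygous animals at 17 dpp (10 genes, 95% interval 0.363 to 1.38%, with genes taken as independent). The same heterozygous animals also set which genes rise with age, which favours a low percentage. Of 43 lower genes of the spermatid lists, 9 of them with room to fall, 0 lay below both wild-type animals at 20 dpp and heterozygous animals at 17 dpp. In the knockout 213 genes were higher and 35 lower than in both of these groups, 248 of the 1310 called against heterozygous animals at 17 dpp. With only 17 and 20 dpp sampled, this cannot speak against a delay, since a transcript may peak or dip between these ages. Both comparisons also share the knockout animals. For the BD1 deletion the percentage below heterozygous animals at 17 dpp was 5.42% (11 of 203, 2.74 to 9.49%), which leaves a delay alone open on either side of the bound of 5%.

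That bound needs a reserve. The test was first run on all genes, with 0.681% in the knockout and 1.96% in the BD1 deletion, both under 5%. The restriction to genes with room to fall was set after those values were seen, because genes near background cannot fall further. It moved the BD1 value across 5%, and the heterozygous animals of that test belong to the other line, from which the BD1 line also differs in genes such as Wdfy1 and Supt16. A block of development at one stage was not tested against a delay. Other splits of the knockout line at 20 dpp called up to 5419 genes, and of 35 splits only the real split reached 6927. That is under the bound set before, but it is the smallest share that 35 splits allow, so chance was not firmly excluded. The split of 5419 set knockout animal 152 with the wild types. In the BD1 line 3 of 35 splits reached the real 1110, up to 4019, and chance could not be excluded by these splits. They mixed animals across litters 4, 5 and 6, each of which held homozygous and control animals. They therefore did not test the effect within litters. The split of 4019 set control animal 191 with the homozygous animals, and another, of 3812, joined 191 with 193 and 197, so these splits follow a structure of the samples in which 191 lies near the mutants, and the count was 3428 without it. Animals 191 and 193 share litter 4, and with litter as a block 2502 genes were called.

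The second pattern is the set of calls at 17 dpp. Litter was excluded as their only cause, since 153 of 154 genes stayed called with litter as a block. Against a single less mature animal, 122, as their only cause, 50 genes were still called without it, 30 of them among the 131 lower genes. Those 131 kept a median of 0.793 of their change (0.563 to 1.11), and 131 of 131 kept their sign. They were chosen with the remaining animals included, which favours both values, so neither value excludes that cause. A delay in maturation is consistent with the correlation across genes of -0.483 between the effect and the age axis (-0.628 to -0.299 over 20 splits of the heterozygous animals). Of 100 splits 3 called as many genes as the real 154, under the bound set before. These splits also mixed animals across litters 7, 8 and 9, each of which held knockout and heterozygous animals. Chance was not clearly excluded, since a fit of the knockout and heterozygous animals alone called only Brdt. The highest other split, 454, had animal 121 in place of 72 and was several times the real count, a structure of the samples. A further split of 388 joined animals 116, 121 and 122 of litter 9 with 129, and the count with litter as a block was 1270.

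The third pattern is the higher level of chromosome X transcripts in the knockout at 20 dpp. Their median change of 0.68 came with an age axis on which X genes fell more (-0.74) than autosomal genes (-0.22). After removal of the age trend by a smooth curve the excess of X genes was 0.147, over the bound of 0.1 set before with each animal left out (0.119 to 0.176). Single autosomes lay between -0.0330 and 0.0286, and autosomal genes matched to X genes on the age axis gave an excess of 0.166. Leaving out 1 animal at a time understates the spread, and that makes the bound as written too easy to pass. A jackknife over animals gave an SE of 0.0415 and a 95% interval of 0.0659 to 0.228, and for the matched genes 0.0932 to 0.239. Both intervals lie above 0, but both still hold 0.1. Both forms take the age axis as free of error, and X genes fall more on it, which favours an excess. They therefore do not decide against the age trend as the whole cause. In the BD1 deletion the excess was 0.149 before and -0.0490 after removal of the age trend (-0.0883 to -0.00980), so no excess beyond age was left there. A straight line gave -0.00331, and -0.0229 corrected for error in the age axis, but the matched autosomal genes lay at -0.107 around that line, so it described the trend poorly and was given no weight. A change of cell mixture with maturation and a change of the X itself cannot be told apart at the bound set, because the spread over animals is wider than the margin above it.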

How the results depend on the processing

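Alternatives on scan brightness, both animals of the lowest testis weight, litter 4, multi-copy genes, the centre of the fold changes and the form of the weight test were chosen after seeing the data. Arrays limit the values through signal over background, so falls near the lowest detected signal are bounds. The Brdt change kept its direction in each setting run, from -3.11 to -1.82 in the knockout at 17 dpp, -3.95 to -3.19 at 20 dpp and -1.33 to -0.72 in the BD1 deletion. The cause of the differences that follow was not tested, except where fewer arrays or genes, or a 2-fold minimum, give fewer calls by construction. A block of slides was not run, since slides are not named in the files used here.

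Counts are of called genes, except with every probe, where they are of called probes. With the authors' matrix the knockout at 17 dpp had 96 and the difference between alleles 95; without background correction 90 and 95. No detection filter gave 99 at 17 dpp. With the animal as a random block there were 465 at 17 dpp, 2541 in the BD1 deletion, 296 between alleles and 2378 shared by both alleles. With all arrays as separate replicates these were 810, 4803, 500 and 4343, and 712 between control groups. With a replicate block they were 971, 5111, 772, 4625 and 886, and 4083 between ages of the knockout effect. Arrays of 1 number correlated over 0.1 in 4, 4 and 5 of 6 pairs (knockout at 17 and 20 dpp, BD1 deletion), and best with their own number in 3, 2 and 5, a hint from the data, not the design. The numbers were not taken as pairs, since the lowest pair was at -0.148, -0.126 and -0.0453. With 1 array per animal 667 differed between control groups. Litter as a block gave 1270 at 17 dpp, 2502 in the BD1 deletion and 2187 shared.

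A fit of only the groups compared gave 1 gene at 17 dpp, 331 in the BD1 deletion, 52 between alleles, 58 between control groups and 326 shared. Array quality weights gave 6096 in the BD1 deletion, 4510 between ages, 283 between alleles, 679 between control groups and 5349 shared. Every probe, counting probes and not genes, gave 257 at 17 dpp, 11407 in the knockout at 20 dpp, 219 between alleles, 15834 with age, 359 between control groups and 9852 against age. A 2-fold minimum gave 94 at 17 dpp, 1384 and 479 at 20 dpp, 862 between ages, 2246 with age, 54 between control groups, 459 shared and 1163 against age, and 2-fold age genes 2011 against age.

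In the BD1 deletion wild-type controls only gave 2972 genes and 2740 shared, and heterozygous controls only 326 and 316, with Brdt at -0.72 and not called. Litter 1 alone gave 4401 in the knockout at 20 dpp and 3911 against age, and the 6 dimmer arrays 4357 and 3846. Brightness as a block gave 2267 shared. At 17 dpp testis weight as a covariate gave 757, and leaving out both animals of the lowest weight 232. With an estimated correlation 0 gene lists were called. With each array as a value the testis weight difference at 17 dpp reversed to -0.333 mg and that of the knockout at 20 dpp was -2 mg, past the threshold by counting repeated arrays as animals.

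With each animal left out the counts were 50 to 483 for the knockout at 17 dpp, 5562 to 6842 at 20 dpp, 515 to 3428 for the BD1 deletion, 1305 to 3461 between ages, 31 to 303 between alleles, 8636 to 9082 with age, 64 to 232 between control groups, 498 to 3174 shared, 5014 to 6026 against age and 31 to 36 gene lists. Brdt ranged from -3.10 to -2.63, -3.86 to -3.51 and -1.23 to -0.90. The lowest and highest came without animals 122 (as low without 127) and 121, 157 and 152, 193 and 191, 157 and 122, 222 and 196, 157 and 191, 157 and 196, 193 and 191, 157 and 152, and 122 and 191 for the counts in that order.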

Other observations

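The genes of the first paragraph, the test of linked variation, and the counts of splits taken in either direction were chosen only after the result was seen, while the other splits of the animals were set before.

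Some genes lay outside the levels of the controls at both ages sampled. In the knockout at 20 dpp 213 genes were higher than in both wild-type animals of that age and heterozygous animals at 17 dpp (limma), such as Aqp2 (1.37 against the nearer group), Pbld2 (1.28), Kcnd2 (1.28), Ccn5 (1.16) and Cyp11a1 (1.00), a steroidogenic enzyme gene. Klk1b21, Klk1b27, Klk1b26 and Klk1b24 were also among these, with the reserve of near-identical copies. Lower than both were 35 genes, such as Brdt (-1.19), Svop (-0.83), Capsl (-0.82) and Jakmip2 (-0.80). In the BD1 deletion 30 genes were higher than both, such as Pbld2 (1.18) and Hspb8 (1.07), and 23 lower, led by 4930515G01Rik (-1.53), Wdfy1 (-1.23), Supt16 (-1.21) and Atp10a (-0.98). The animals at 17 dpp belong to the other line, so differences between the lines enter these counts, and Wdfy1 and Supt16 also differed between the control groups. Both comparisons share the mutant animals.

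A candidate explanation of the differences between the control groups is DNA variation linked to the lines, since 33 of 400 genes tested on chromosome 14 were called against 6.85 expected (Fisher's exact test, adjusted p = 7.13e-13), and 30 of 579 on chromosome 17 against 9.92 (exact, adjusted p = 4.71e-07). Other splits of these animals called up to 347 genes, 4 of 35 reached the real 197, and chance could not be excluded for the total. The count was 64, 75 and 85 without wild-type animals 157, 146 and 149, and 115 without control animal 219.

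For controls at 20 against 17 dpp only the real split of 100 reached 8927, with 8828 as the highest other. That is under the bound set before, and is the smallest share that these splits allow. The next 2 counts were taken in either direction, since splits that set the wild types in the place of the knockouts run the reverse way. The genes of the knockout that moved against age numbered 6044, with 4958 as the highest of the other splits and 1 of 35 as large. The calls shared by both alleles numbered 1059, with 955 as the highest other and 1 of 35 as large. For both counts the 1 is the real split itself, the smallest share that 35 splits allow. Since this form was also set after the result was seen, chance was not firmly excluded for either. Both highest splits set knockout animal 152 with the wild types and so nearly reverse the real one. Counts of gene lists called by camera could not be told from chance: 19 of 100 splits reached the real 12 at 17 dpp (highest other 14), 19 of 35 the real 11 in the knockout at 20 dpp (15), and 13 of 35 the real 11 in the BD1 deletion (14).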
